A study of Mus musculus with 18 samples.

How the data were processed

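RNA-seq was measured in 18 mouse samples of Rx:GFP knock-in embryonic stem cells (ESCs), a line whose Rax (Rx) locus carries a GFP reporter, and of embryoid bodies (EBs) grown from them by the SFEBq method, a serum-free aggregation culture. The labels give 9 groups of 2 samples and call the members of each pair biological duplicates. No further detail of separate cultures is given, so p-values measure only the spread between these pairs. Libraries were made with the Illumina TruSeq protocol as single-end libraries, per the labels.

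The authors deposited one transcript table per sample with an FPKM (fragments per kilobase of transcript, scaled to the mapped reads) and a coverage value per transcript, made by Cufflinks per the file headers. Per the submitters' processing notes the tools were HISAT2 2.0.0, STAR 2.7.3a and Cufflinks 2.2.1 with the mm10 mouse genome; which aligner served which sample is not given in the sources used here. FPKM are not counts, so no count test was used. Coverage divided by FPKM gave the depth of each library: the lowest coverage values stood for one read of 51 bases in 6 libraries (EB parental, EB DKO-A and EB DKO-B) and one fragment of 298 or 299 bases in the others. The implied totals were 50.4 to 73.8 M reads in the first set and 32.5 to 49.0 M fragments in the second. The labels call all libraries single end, so the 2 read layouts are inferred from the values. FPKM sums were 511561 to 536982 in the 6 libraries and 380418 to 404374 in the 11 other libraries with mouse gene models. Comparisons between the layouts can carry technical differences and are named where they occur.

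The file of replicate 2 of the EB DKO S91KY191F group holds human gene models and was left out of all tests, which leaves 17 samples, 1 of them in that group. The design fixed beforehand asked for genes present in every file and for 18 samples; genes of the 17 mouse-model files were used instead, with 8 residual degrees of freedom. Gene FPKM was the sum over a gene's transcripts, with no further scaling. Of 30942 genes in the mouse-model files, 30823 had a symbol in the gene name table used, and 30822 overlapped their position in the mm10 annotation GENCODE vM21. Genes were tested when the longest transcript had at least 300 nt and FPKM was at least 1 in at least 2 samples, which left 13297 genes. Values were log2(FPKM + 1), so fold changes understate those of low genes. The model had 9 group means over all samples, because each group has at most 2, and was fitted in limma 3.58.1 (R 4.3.3) with a moderated test, an intensity trend and Benjamini-Hochberg adjustment. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

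Gene lists were fixed before the data were examined: 21 lists with 500 different genes in all, covering naive and general pluripotency, formative and primed epiblast, primitive streak and mesoderm, neuroectoderm and eye field, definitive endoderm, primitive and visceral endoderm, trophoblast, feeder and fibroblast, p53 targets, cytosolic ribosomal proteins, WDR5 partners and MLL/SET1 complexes, Hox clusters, Wnt feedback targets, 2-cell-like, germline genes, imprinted genes, integrated stress response and amino acid synthesis, glycolysis and hypoxia response, cell cycle and proliferation, mitochondrially encoded mRNAs and immediate early genes. They were tested with camera in limma at a preset correlation of 0.01, with the estimated correlation beside it, and adjusted over the 21 lists of a comparison. Aldoa counts as 2 list members because 2 gene identifiers carry that symbol. Not all fixed members were tested: 4 of 39 in the Hox clusters, 8 of 31 for primitive streak and mesoderm and 8 of 16 in the 2-cell-like list. Results on these lists hold for the tested members only. Of the list members, Cdt1, Dux, Foxc2, Foxf1, Rian, Rpl13, Slc7a5, Tubb3 and Zscan4a were not analysed here. The rule for named genes, also fixed beforehand, took Wdr5, Trp53 and Rax, the 5 genes with the largest rise and the 5 with the largest fall among protein-coding genes past the threshold (mean FPKM of at least 5 on the higher side, no overlap between the sides, predicted gene models left out), and up to 2 called members of each list; secondary comparisons took 3 in each direction. A gene that this rule took is not reported here. No comparison has 3 samples in each group, so no count over other splits of the samples was made. For 26 genes a library was listed at 0 while another reached at least 20 FPKM, which can be a failed estimate; where such a library enters a comparison the gene is given per library without a fold. Genes with near-identical copies, among them the Zscan4 cluster, Hspa1a with Hspa1b, Rhox genes and ribosomal protein retrocopies, are uncertain, since the way Cufflinks divided shared reads is not given in the sources used here.

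Replicates were compared before averaging. Pearson correlations of log2 values within pairs were 0.99353 to 0.99881. The reads implied for genes with 1 transcript and at least 100 reads differed within every pair by more than sampling noise, with a median chi-square per gene of 0.79 to 13.45 against 0.455 under sampling noise alone, so no pair was taken as the same library deposited again. This does not show that the cultures were separate. Replicate numbers were not taken as pairing samples across groups. The fit was tested on simulated data with 200 changed genes of 13297, drawn only from genes of higher mean value. The noise was independent per gene at its fitted spread. The shares below therefore cover neither low genes nor error from differences between lines or cultures. For EB DKO against parental, 97% of changes of log2 0.5 and 100% of changes of log2 1 and 2 were recovered with 2.9% of calls false. For EB S91KY191F against vector, the shares were 86.6%, 94% and 100% with 4.1% false. For ESC S91KY191F against WDR5-WT they were 94%, 100% and 100% with 5.3% false, and for the rescue 95.5%, 100% and 100% with 2.5% false. Alternatives covered the pseudocount, the filter, the scaling, the samples in the fit, array weights, a replicate block and leaving out each replicate. Further ones were added after the data were seen. List medians were also taken under 3 other scalings, and no list that passed in a comparison changed the sign of its median there. Sizes did change. With quantile normalization the median of cytosolic ribosomal proteins went from -0.595 to -0.035 in EB vector against DKO and from 0.187 to 0.049 in DKO-A against DKO-B. It went from 0.205 to 0.063 in EB S91KY191F against vector, and from -0.468 to -0.325 in EB DKO against parental.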

Results

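The study compared embryonic stem cells (ESCs) and embryoid bodies (EBs) labelled as parental, as knockout of p53 (gene Trp53), or as double knockout of Wdr5 and p53. WDR5 is a core subunit of the MLL/SET1 histone H3 lysine methyltransferase complexes. The EB groups were the parental line, double knockout (DKO) lines A and B, and DKO cells carrying a backbone vector or WDR5 with the S91K and Y191F changes (S91KY191F). The ESC groups were DKO cells with wild-type WDR5 or S91KY191F, and p53 knockout clones C9 and H9. Each group had 2 libraries, except the EB S91KY191F group with 1 usable library. Between 10734 and 11478 genes reached 1 FPKM per mouse-model library. Group values are means ± SD with n = 2. The EB S91KY191F group has n = 1 and no SD, and tests with it assume the spread of the other groups.

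The targeted genes were read first. Wdr5 (ENSMUSG00000026917, chromosome 2, 27515157 to 27536535, mm10, plus strand) stood at 65.8 ± 2.28 FPKM in parental EBs, 56.0 ± 2.67 in DKO-A, 49.0 ± 1.89 in DKO-B, 46.5 ± 0.764 with vector and 33.0 with S91KY191F. In ESCs Wdr5 was 50.3 ± 2.38 FPKM with wild-type WDR5, 64.9 ± 1.35 with S91KY191F, 146 ± 0.294 in clone C9 and 147 ± 2.19 in clone H9. The sums include a second Wdr5 transcript, at 11.8 to 15.9 FPKM in the 51-base libraries and at most 0.215 in the others with mouse gene models. The main transcript alone stood at 51.6 and 50.7 FPKM in parental EBs, 42.0 and 39.5 in DKO-A and 33.3 and 32.7 in DKO-B. With vector it was at 46.2 and 45.2, above both DKO lines, and with S91KY191F at 32.7 in EBs. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand), which encodes the tumour suppressor p53, stood at 111 ± 7.26 FPKM in parental EBs, 12.7 ± 0.923 in DKO-A, 23.0 ± 0.208 in DKO-B, 37.5 ± 0.00186 with vector and 41.4 with S91KY191F. In ESCs Trp53 was 20.5 ± 0.196 FPKM with wild-type WDR5, 22.2 ± 0.812 with S91KY191F, 34.0 ± 1.60 in C9 and 109.6 ± 1.57 in H9. The p53 knockout clones differed in Trp53 RNA by a log2 fold change of -1.66 ± 0.0561 (SE, adjusted p = 3.08e-10) for C9 against H9, and H9 lay at the level of parental EBs, from which it differs in state and read layout. The edited exons are not given in the sources used here and the values cover whole genes or whole transcripts. RNA levels of Wdr5 and Trp53 therefore do not test the genotype labels. Ccng1, a direct p53 target, was at 62.2 and 62.4 FPKM in the parental EB libraries and between 0.947 and 5.42 FPKM in the 15 other libraries with mouse gene models. Cdkn1a, another p53 target, was at 9.77 and 9.27 FPKM in parental EBs and between 0.197 and 1.48 FPKM in the 7 other EB libraries. In ESCs it was 12.9 ± 0.0818 FPKM with wild-type WDR5, 14.3 ± 0.997 with S91KY191F, 26.8 ± 0.654 in C9 and 32.9 ± 0.110 in H9. Of the libraries set beside parental EBs here, only those of DKO-A and DKO-B share the 51-base layout.

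**Figure D1:**
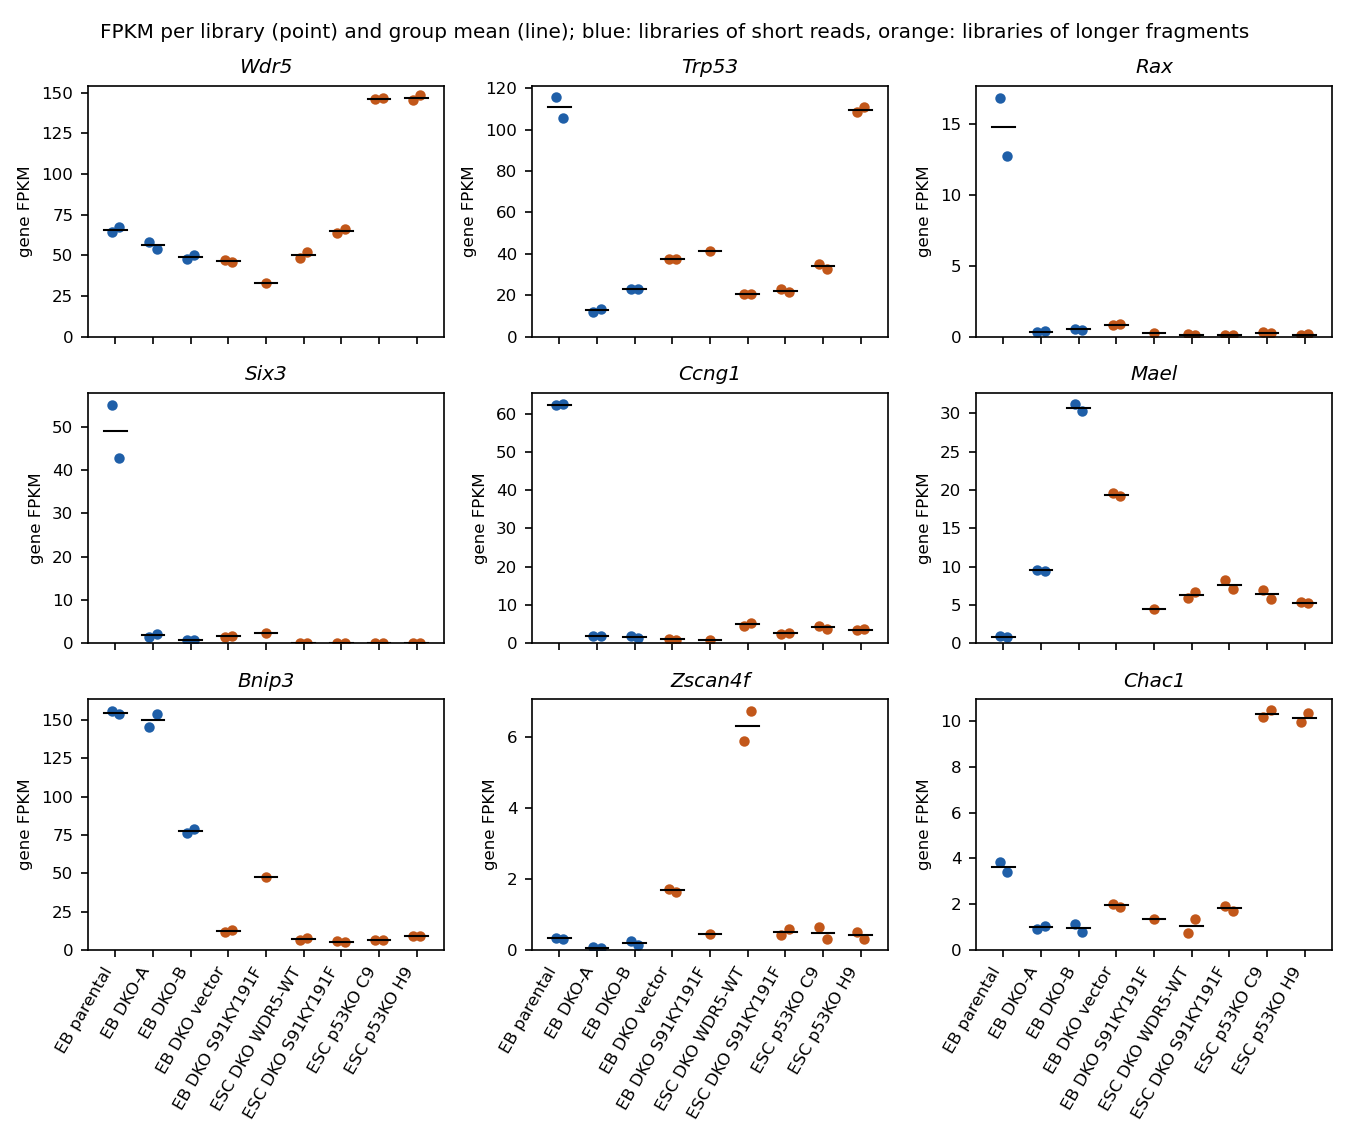
FPKM of 9 genes in each library (points) with group means (lines), for the 9 groups on the horizontal axis. Blue points are libraries of 51-base reads and orange points libraries of 298 or 299 bases per fragment, and Ccng1 is at 62.2 and 62.4 FPKM in parental EBs.

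Loss of both genes was examined in EBs by setting DKO-A and DKO-B (4 libraries) against parental EBs (2 libraries). The SEs and p-values of this comparison come from the spread within pairs of libraries. They do not cover differences between lines, and A and B themselves differed in 7744 of 13297 genes. They therefore do not measure how far a change belongs to the genotype. Rax (ENSMUSG00000024518, chromosome 18, 65934639 to 65939089, minus strand), an eye-field transcription factor, fell from 14.8 ± 2.91 FPKM to 0.349 ± 0.0336 in A and 0.505 ± 0.0926 in B, a log2 fold change of -3.46 ± 0.0863 (SE, adjusted p = 4.01e-13). Six3, a forebrain and eye homeobox gene, fell by 4.51 on the log2 scale, and Lhx5, a forebrain LIM-homeobox gene, fell by 3.98. Ccng1 fell by 4.51, Lmo1, a LIM-only transcriptional regulator, fell by 4.70, and Irs4, an insulin receptor substrate, fell by 3.82. Germline genes rose, with a log2 fold change of 3.29 ± 0.0726 (SE, adjusted p = 1.27e-13) for Mael, a piRNA pathway factor, and 3.02 for Meioc, a meiosis gene. Apela, a peptide ligand of the apelin receptor, had a log2 fold change of 3.97 ± 0.0750 (SE, adjusted p = 4.13e-14). Foxd3, a transcription factor of epiblast and neural crest, was at 2.96, and the heat shock gene Hspa1b was at 3.52, an uncertain value because Hspa1a is nearly identical.

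Of 19 tested germline genes, 17 rose, 1 fell and 1 did not pass (the same numbers adjusted over the list alone), with adjusted p = 4.18e-07 and adjusted p = 0.0249 with an estimated correlation. Besides Mael, Ddx4, the germ cell helicase Vasa, was at a log2 fold change of 2.58. Among 30 tested p53 targets, 1 rose, 24 fell and 5 did not pass (the same numbers adjusted over the list alone), with adjusted p = 2.81e-05 and adjusted p = 0.0249 with an estimated correlation. Phlda3, an Akt repressor, was at -3.77. Of 22 naive and general pluripotency genes, 17 rose, 1 fell and 4 did not pass (the same numbers adjusted over the list alone), with adjusted p = 2.18e-05 and adjusted p = 0.523 with an estimated correlation. Its members Dppa2 and Dppa3 were at 2.39 and 2.34. Of 19 neuroectoderm and eye field genes, 4 rose, 14 fell and 1 did not pass (5 and 14 adjusted over the list alone), with adjusted p = 0.0321 and adjusted p = 0.523 with an estimated correlation. In the integrated stress response and amino acid synthesis list, of 18 genes, 2 rose, 14 fell and 2 did not pass (the same numbers adjusted over the list alone), with adjusted p = 0.0199 and adjusted p = 0.523 with an estimated correlation. Atf4, its central transcription factor, was at -2.18.

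Of 78 cytosolic ribosomal proteins, 12 rose and 53 fell (13 and 53 adjusted over the list alone), with adjusted p = 0.00313 and adjusted p = 0.785 with an estimated correlation. Rpl37a was at a log2 fold change of -2.49. Of 22 WDR5 partners and MLL/SET1 complex members, 13 rose and 5 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0321 and adjusted p = 0.523 with an estimated correlation. The core subunit Ash2l was at 1.14. Ash2l and Apela lie on chromosome 8, whose expressed genes had a median log2 fold change 0.417 above that of all other genes. Of 22 glycolysis and hypoxia response genes, 5 rose and 14 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0485 and adjusted p = 0.527 with an estimated correlation. Vegfa, an angiogenic growth factor, was at -1.56. Of 11 immediate early genes, 9 rose and 2 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0458 and adjusted p = 0.523 with an estimated correlation. Klf6 was at 1.37 and Egr1 at -1.32. The glycolysis and the immediate early calls were each lost with a replicate block (adjusted p = 0.0518), and the immediate early call also with median-of-ratios scaling (adjusted p = 0.0606).

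The other lists did not pass in this comparison. Of 17 formative and primed epiblast genes, 7 rose and 8 fell (the same numbers adjusted over the list alone), with adjusted p = 0.687. Of 8 primitive streak and mesoderm genes, 4 rose and 1 fell (the same numbers adjusted over the list alone), with adjusted p = 0.400. For definitive endoderm, of 9 genes, 2 rose and 2 fell (the same numbers adjusted over the list alone), with adjusted p = 0.715. For primitive and visceral endoderm, of 15 genes, 4 rose and 8 fell (the same numbers adjusted over the list alone), with adjusted p = 0.517. For trophoblast, of 15 genes, 8 rose and 4 fell (the same numbers adjusted over the list alone), with adjusted p = 0.474. Of 10 feeder and fibroblast genes, 7 rose and 2 fell (the same numbers adjusted over the list alone), with adjusted p = 0.181. Of 12 Wnt feedback targets, 2 rose and 5 fell (the same numbers adjusted over the list alone), with adjusted p = 0.772. In the 2-cell-like list, of 8 genes, 0 rose and 3 fell (0 and 1 adjusted over the list alone), with adjusted p = 0.682. Of 20 imprinted genes, 8 rose and 10 fell (the same numbers adjusted over the list alone), with adjusted p = 0.772. Nnat was at -2.40 and Mest at -2.23. Of 25 cell cycle and proliferation genes, 11 rose and 10 fell (the same numbers adjusted over the list alone), with adjusted p = 0.715. In the Hox clusters, of 4 genes, 0 rose and 0 fell (the same numbers adjusted over the list alone), with adjusted p = 0.756. Of 11 mitochondrially encoded mRNAs, 3 rose and 1 fell (3 and 0 adjusted over the list alone), with adjusted p = 0.715. The median, the mean and the test differed in sign for definitive endoderm (median -0.008, mean 0.172, test up), cell cycle (0.079, -0.003, up) and mitochondrially encoded mRNAs (-0.038, 2.001, up). The mean of the last list includes genes listed at 0 in a library.

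The mitochondrial mRNA mt-Co1 is listed at 0 in both parental libraries and 1 DKO-A library, and at 8232, 7216 and 7949 FPKM in the other DKO libraries. Likewise mt-Co3 is listed at 0 in parental replicate 1 and at 7998 FPKM in replicate 2, and without replicate 1 its log2 fold change was -0.0645 (adjusted p = 0.537). Across all genes, 10337 of 13297 genes passed in limma, 4541 higher and 5796 lower, and 1771 of them changed by a fold of 2 or more, 501 higher and 1270 lower. Of all calls 43.9% were higher, or 51.8% after quantile normalization. All 6 libraries share the 51-base layout.

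**Figure D2:**
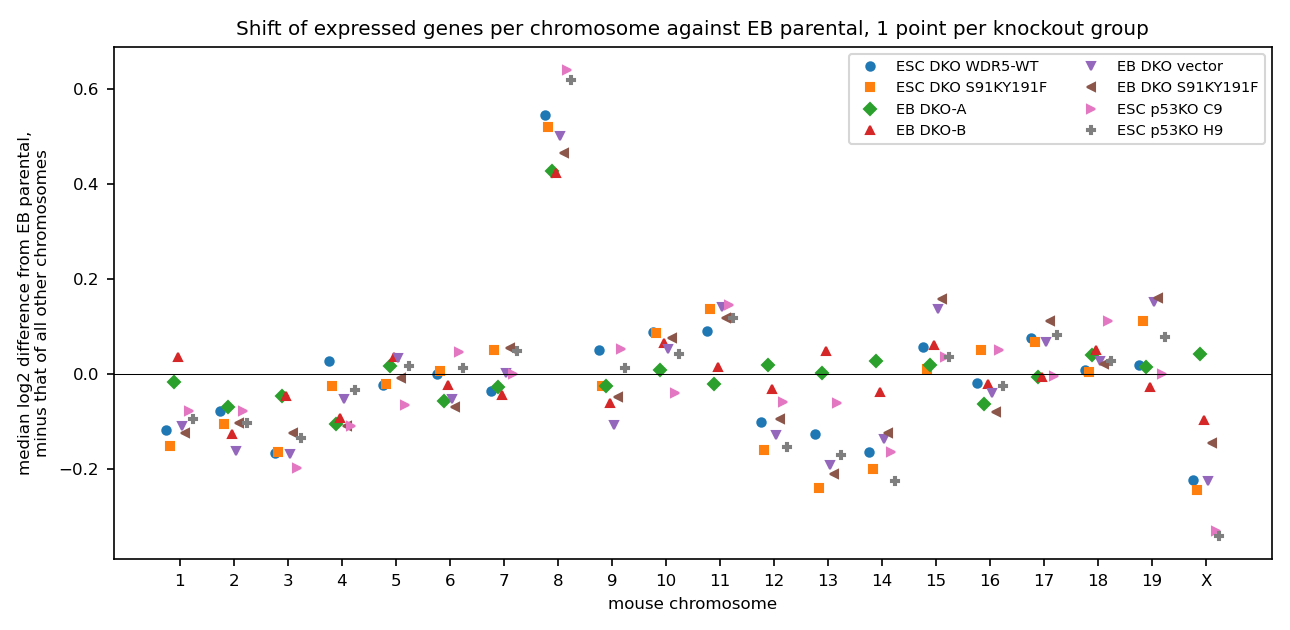
For each mouse chromosome (horizontal axis), the median log2 difference of its expressed genes from parental EBs minus that of all other genes (vertical axis), with 1 point per knockout group. Chromosome 8 lies between 0.423 and 0.639 in the 8 groups, and the largest absolute value elsewhere is 0.34. Only DKO-A and DKO-B share the read layout of parental EBs, and the 4 ESC groups differ from them in state too.

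DKO-A and DKO-B were also compared with each other and singly with parental EBs. Against B, line A was lower in Muc3, a membrane mucin, by a log2 fold change of -3.11 ± 0.0735 (SE, adjusted p = 3.50e-12), in Foxn4, a forkhead factor, at -3.05, and in Hspa1a at -3.09. It was higher in Hesx1, a forebrain homeobox gene, at 2.64 ± 0.120 (SE, adjusted p = 1.33e-09). Hist1h2ah at 2.65 and Rps27rt at 3.73 were also higher, but these and Hspa1a have near-identical copies and are uncertain. Of 19 germline genes in A against B, 0 rose and 17 fell (the same numbers adjusted over the list alone), with adjusted p = 1.47e-09 and adjusted p = 0.0221 with an estimated correlation. Of 22 glycolysis and hypoxia response genes, 20 rose and 0 fell (the same numbers adjusted over the list alone), with adjusted p = 9.15e-14 and adjusted p = 0.0313 with an estimated correlation. Of 10 feeder and fibroblast genes, 0 rose and 10 fell (the same numbers adjusted over the list alone), with adjusted p = 1.12e-04 and adjusted p = 0.0561 with an estimated correlation. Among 78 cytosolic ribosomal proteins in A against B, 35 rose and 4 fell (34 and 4 adjusted over the list alone), with adjusted p = 9.06e-07 and adjusted p = 0.686 with an estimated correlation. Among 22 pluripotency genes in A against B, 1 rose and 17 fell (2 and 18 adjusted over the list alone), with adjusted p = 1.11e-04 and adjusted p = 0.414 with an estimated correlation. In all, 7 of 21 lists passed in A against B, 2 of them with an estimated correlation too. Between the lines, 7744 of 13297 genes passed in limma, 2816 higher and 4928 lower, and 363 of them changed by a fold of 2 or more, 83 higher and 280 lower. Of the calls, 36.4% were higher in A, or 51% after quantile normalization.

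For A against parental EBs, 9532 of 13297 genes passed in limma, 3667 higher and 5865 lower, and 1411 of them changed by a fold of 2 or more, 299 higher and 1112 lower. Of these calls 38.5% were higher, or 52.2% after quantile normalization, which moved the median of all genes from -0.096 to 0.019. For B against parental EBs, 10378 of 13297 genes passed in limma, 4932 higher and 5446 lower, and 2503 of them changed by a fold of 2 or more, 961 higher and 1542 lower. Of the calls 47.5% were higher, or 51.5% after quantile normalization. Six3, Lmo1 and Ccng1 were at -4.15, -4.71 and -4.45 in A and at -4.87, -4.70 and -4.58 in B. Apela was at 3.27 in A and 4.67 in B.

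Some lists that passed with both lines together did not pass in each line. Of 22 glycolysis and hypoxia response genes against parental EBs, in A 7 rose and 9 fell (the same numbers adjusted over the list alone), with adjusted p = 0.803 and adjusted p = 0.897 with an estimated correlation, and in B 2 rose and 15 fell (2 and 16 adjusted over the list alone), with adjusted p = 4.17e-04 and adjusted p = 0.369 with an estimated correlation. Of 78 cytosolic ribosomal proteins, in A 19 rose and 46 fell (20 and 46 adjusted over the list alone), with adjusted p = 0.170 and adjusted p = 0.897 with an estimated correlation, and in B 8 rose and 56 fell (the same numbers adjusted over the list alone), with adjusted p = 4.42e-05 and adjusted p = 0.639 with an estimated correlation. Of 19 neuroectoderm and eye field genes, in A 2 rose and 13 fell (2 and 14 adjusted over the list alone), with adjusted p = 0.00693 and adjusted p = 0.534 with an estimated correlation, and in B 5 rose and 12 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0581 and adjusted p = 0.532 with an estimated correlation. Of 11 immediate early genes, in A 5 rose and 2 fell (the same numbers adjusted over the list alone), with adjusted p = 0.126 and adjusted p = 0.622 with an estimated correlation, and in B 8 rose and 3 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0802 and adjusted p = 0.532 with an estimated correlation.

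DKO EBs with S91KY191F were set against those with the vector (1 library against 2). Across genes, the log2 fold changes correlated with those of DKO-A against DKO-B, which share a genotype label, at a Spearman rho of 0.709. The changes below can therefore not be told apart from a difference between lines. The lactate exporter gene Slc16a3 was higher with S91KY191F, at a log2 fold change of 2.24 ± 0.0992 (SE, adjusted p = 2.69e-09). Also higher were Bnip3, a hypoxia-induced mitophagy receptor, at 1.89, Gng3, a G protein subunit, at 2.08, Cldn7, a claudin, at 1.77, and Msi1, a neural RNA-binding protein, at 1.76. Muc3 was lower, at -3.18 ± 0.0901 (SE, adjusted p = 1.19e-10). Foxn4 was at -2.96, Hspa1a at -2.39, the germline gene Tex19.1 at -2.26 and the homeobox gene Msx1 at -2.16. Rax stood at 0.221 FPKM with S91KY191F and 0.854 ± 0.0551 with vector, a log2 fold change of -0.60 ± 0.122 (SE, adjusted p = 0.00105).

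Of 19 germline genes with S91KY191F against vector, 0 rose, 16 fell and 3 did not pass (the same numbers adjusted over the list alone), with adjusted p = 2.01e-11 and adjusted p = 0.0112 with an estimated correlation. Among 22 glycolysis and hypoxia response genes, 17 rose, 0 fell and 5 did not pass (the same numbers adjusted over the list alone), with adjusted p = 2.70e-09 and adjusted p = 0.0807 with an estimated correlation. Tpi1, a glycolytic enzyme, was at 1.58. Of 22 pluripotency genes, 1 rose, 18 fell and 3 did not pass (2 and 18 adjusted over the list alone), with adjusted p = 1.86e-06 and adjusted p = 0.332 with an estimated correlation. For the formative and primed epiblast, of 17 genes, 12 rose, 3 fell and 2 did not pass (the same numbers adjusted over the list alone), with adjusted p = 0.00223 and adjusted p = 0.332 with an estimated correlation. Sox3 was at 1.36. In the 2-cell-like list, of 8 genes, 0 rose and 8 fell (the same numbers adjusted over the list alone), with adjusted p = 1.28e-04 and adjusted p = 0.0807 with an estimated correlation. Of 78 cytosolic ribosomal proteins, 27 rose and 7 fell (the same numbers adjusted over the list alone), with adjusted p = 2.99e-04 and adjusted p = 0.634 with an estimated correlation. Of 10 feeder and fibroblast genes, 4 rose and 4 fell (the same numbers adjusted over the list alone), with adjusted p = 0.744. Over all genes, 6606 of 13297 genes passed in limma, 2847 higher and 3759 lower, and 325 of them changed by a fold of 2 or more, 122 higher and 203 lower.

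**Figure D3:**
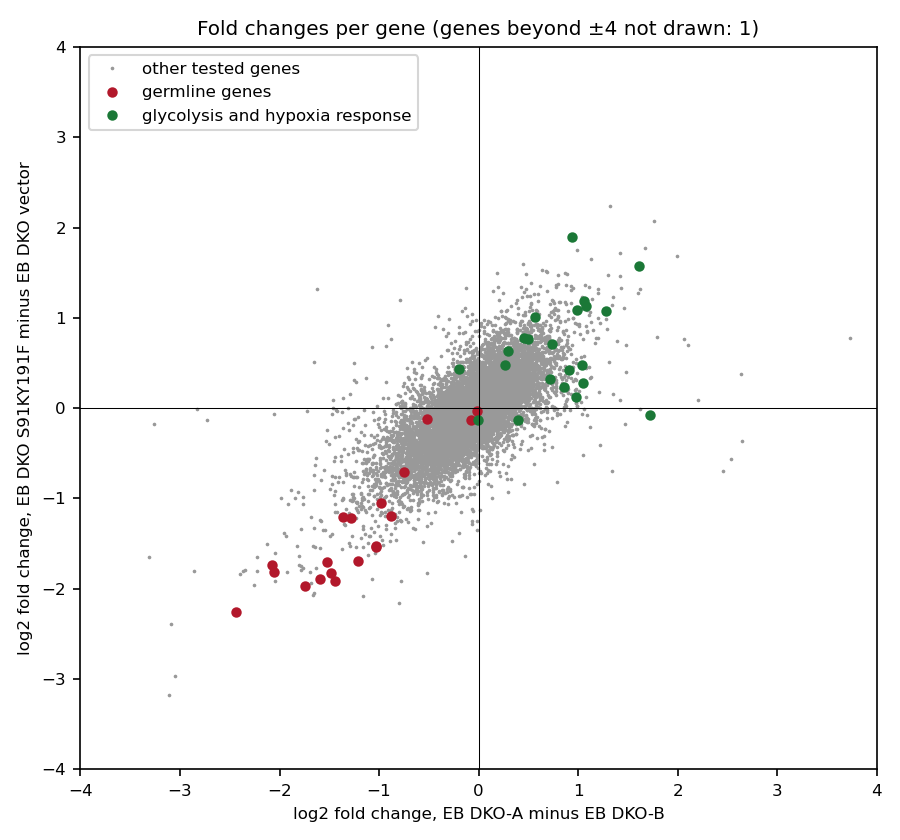
Log2 fold change per gene of DKO-A minus DKO-B (horizontal axis) and of EB S91KY191F minus vector (vertical axis), with 13296 genes drawn and 1 beyond the axes left out. Germline genes are red, with medians of -1.28 and -1.54, and glycolysis and hypoxia response genes are green, with medians of 0.88 and 0.56.

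**Figure D4:**
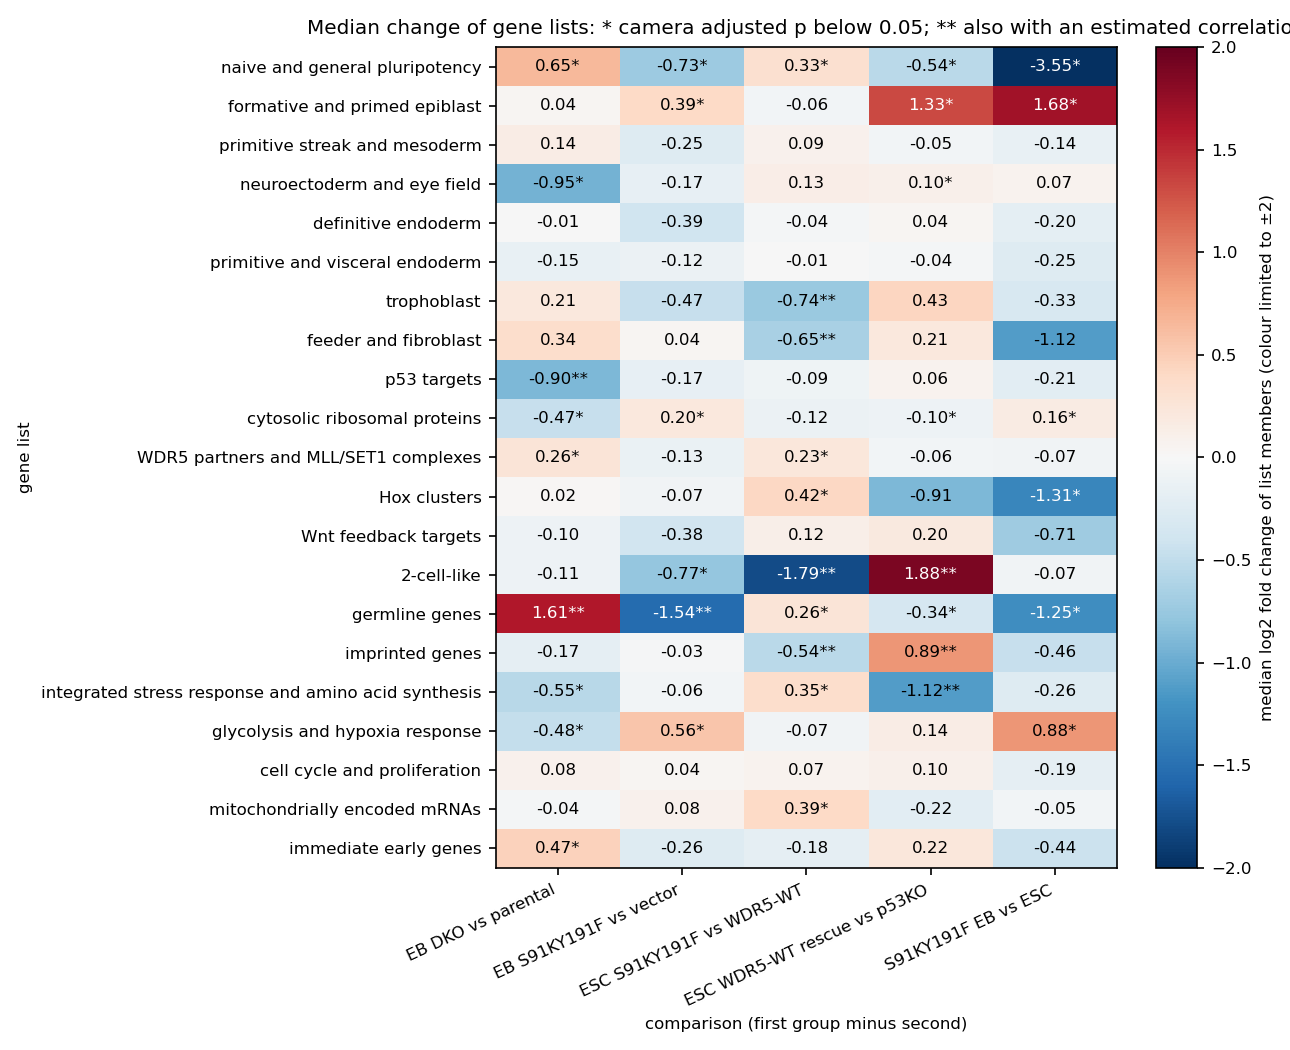
Median log2 fold change of the tested members of 21 gene lists (vertical axis) in the 5 main comparisons (horizontal axis). A star marks camera adjusted p below 0.05 and a double star lists that also pass with an estimated correlation, with germline genes at 1.61 in EB DKO against parental.

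In DKO ESCs kept in 2i and LIF, S91KY191F was compared with wild-type WDR5 (2 libraries each). Hesx1 was higher with S91KY191F, at a log2 fold change of 2.21 ± 0.120 (SE, adjusted p = 1.47e-08). Fcgrt, the neonatal Fc receptor, was at 1.93, Apom, an apolipoprotein, at 1.79, Trpm1, a cation channel, at 1.78 and Ddr2, a collagen receptor, at 1.69. Col1a1, a type I collagen gene, was lower, at 8.77 ± 0.0750 against 49.3 ± 0.840 FPKM, a log2 fold change of -2.36 ± 0.0715 (SE, adjusted p = 2.83e-10). Zscan4f, Zscan4c and Zscan4d, genes of the 2-cell embryo, were at -2.28, -2.09 and -2.08, each uncertain because the copies are nearly identical. Akr1c18, a steroid-metabolizing enzyme, was at -2.01.

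In the 2-cell-like list, of 8 tested genes, 0 rose, 8 fell and 0 did not pass (the same numbers adjusted over the list alone), with adjusted p = 2.00e-09 and adjusted p = 0.0172 with an estimated correlation. Of 10 tested feeder and fibroblast genes, 0 rose, 10 fell and 0 did not pass (the same numbers adjusted over the list alone), with adjusted p = 2.64e-07 and adjusted p = 0.0172 with an estimated correlation. Among 20 tested imprinted genes, 1 rose, 14 fell and 5 did not pass (the same numbers adjusted over the list alone), with adjusted p = 1.15e-06 and adjusted p = 0.0185 with an estimated correlation. Igf2 was at -1.84. For trophoblast, of 15 tested genes, 0 rose, 11 fell and 4 did not pass (the same numbers adjusted over the list alone), with adjusted p = 2.85e-05 and adjusted p = 0.0433 with an estimated correlation. Peg10 was at -1.26. Clones C9 and H9, which share a genotype label, also differed in the feeder, imprinted and trophoblast lists. In C9 against H9, 0 feeder and fibroblast genes rose and 9 fell, 3 imprinted genes rose and 11 fell, and 2 trophoblast genes rose and 9 fell. In the 2-cell-like list 0 rose and 0 fell there. A difference between lines is therefore not excluded for the feeder, imprinted and trophoblast falls with S91KY191F. In the 2-cell-like list it was the group with wild-type WDR5 that stood apart. Against both clones, 8 of its 8 genes rose with wild-type WDR5 (median 1.883), while 0 rose and 0 fell with S91KY191F (median 0.088). Whether the line or its WDR5 sets that group apart was not tested, so a difference between lines is not excluded there either. Of 22 naive and general pluripotency genes, 13 rose and 0 fell (the same numbers adjusted over the list alone), with adjusted p = 8.33e-05 and adjusted p = 0.274 with an estimated correlation. Of 19 germline genes in these ESCs, 11 rose and 1 fell (the same numbers adjusted over the list alone), with adjusted p = 3.48e-04 and adjusted p = 0.0714 with an estimated correlation. For the integrated stress response, of 18 genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone), with adjusted p = 3.48e-04 and adjusted p = 0.206 with an estimated correlation. Of 22 WDR5 partners and MLL/SET1 complex members, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with adjusted p = 0.00142 and adjusted p = 0.206 with an estimated correlation. In the Hox clusters, of the 4 genes tested out of 39 fixed, 3 rose and 0 fell (the same numbers adjusted over the list alone), with adjusted p = 0.00850 and adjusted p = 0.111 with an estimated correlation. Of 11 mitochondrially encoded mRNAs, 6 rose and 0 fell (the same numbers adjusted over the list alone), with adjusted p = 0.00292 and adjusted p = 0.332 with an estimated correlation. Across all genes, 5671 of 13297 genes passed in limma, 2620 higher and 3051 lower, and 176 of them changed by a fold of 2 or more, 78 higher and 98 lower.

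DKO ESCs with wild-type WDR5 (2 libraries) were set against clones C9 and H9 (4 libraries), which the labels give as p53 knockouts only. Here too the SEs and p-values come from the spread within pairs of libraries and do not cover differences between lines. Fgfbp1, an FGF-binding protein, was higher in the rescue, at a log2 fold change of 3.0 ± 0.108 (SE, adjusted p = 2.30e-11). Emb was at 2.97, Slc16a3 at 2.82 and Crmp1 at 2.82. Nupr1, a stress-induced gene, was lower, at -3.61 ± 0.0919 (SE, adjusted p = 1.10e-12). The glutamate transporter Slc1a1 was at -3.23, the NMDA receptor subunit Grin1 at -3.21, Ckmt1 at -3.12 and Crxos at -3.01. Wdr5 itself was at -1.53. Trp53 was at -1.53 over both clones, but at -0.70 against C9 alone and -2.36 against H9 alone.

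In the integrated stress response and amino acid synthesis list, of 18 tested genes, 0 rose, 17 fell and 1 did not pass (the same numbers adjusted over the list alone), with adjusted p = 2.49e-11 and adjusted p = 0.0427 with an estimated correlation. Chac1 was at -2.47 and Pck2 at -2.45. In the 2-cell-like list, of 8 tested genes, 8 rose, 0 fell and 0 did not pass (the same numbers adjusted over the list alone), with adjusted p = 1.88e-06 and adjusted p = 0.0427 with an estimated correlation. Among 20 tested imprinted genes, 16 rose, 3 fell and 1 did not pass (the same numbers adjusted over the list alone), with adjusted p = 5.10e-06 and adjusted p = 0.0427 with an estimated correlation. Mest was at 1.91. For the formative and primed epiblast, of 17 tested genes, 16 rose, 1 fell and 0 did not pass (the same numbers adjusted over the list alone), with adjusted p = 6.00e-08 and adjusted p = 0.0616 with an estimated correlation. Of 22 pluripotency genes, 4 rose and 16 fell (the same numbers adjusted over the list alone), with adjusted p = 2.38e-04 and adjusted p = 0.358 with an estimated correlation. Of 19 neuroectoderm and eye field genes, 9 rose and 2 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0498 and adjusted p = 0.492 with an estimated correlation. That call was lost with a replicate block (adjusted p = 0.0543). Of 19 germline genes in the rescue, 5 rose and 11 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0402 and adjusted p = 0.325 with an estimated correlation. Of 78 cytosolic ribosomal proteins, 1 rose and 21 fell (1 and 13 adjusted over the list alone), with adjusted p = 0.0402 and adjusted p = 0.732 with an estimated correlation. Of 10 feeder and fibroblast genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with adjusted p = 0.315. Over all genes, 8374 of 13297 genes passed in limma, 4411 higher and 3963 lower, and 808 of them changed by a fold of 2 or more, 308 higher and 500 lower.

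Between the clones, C9 was lower than H9 in Igf2, at a log2 fold change of -2.77 ± 0.0803 (SE, adjusted p = 8.17e-11), in Id3 at -1.94 and in the imprinted growth inhibitor Cdkn1c at -1.79. It was higher in Krt42 at 1.23, Camk2b at 1.07 and Lmx1b at 0.98. Of 10 feeder and fibroblast genes in C9 against H9, 0 rose and 9 fell (the same numbers adjusted over the list alone), with adjusted p = 1.24e-09 and adjusted p = 0.0125 with an estimated correlation. Among 78 cytosolic ribosomal proteins in C9 against H9, 0 rose and 23 fell (0 and 19 adjusted over the list alone), with adjusted p = 2.76e-07 and adjusted p = 0.492 with an estimated correlation. Their median was -0.171. Expressed genes under 1000 nt had a median of -0.119 there, against 0.104 for those of 3000 nt or more. Whether transcript length accounts for this list result was not tested. Of 20 imprinted genes in C9 against H9, 3 rose and 11 fell (3 and 12 adjusted over the list alone), with adjusted p = 1.36e-04 and adjusted p = 0.0846 with an estimated correlation. Of 11 immediate early genes in C9 against H9, 0 rose and 7 fell (the same numbers adjusted over the list alone), with adjusted p = 1.92e-04 and adjusted p = 0.111 with an estimated correlation. In all, 9 of 21 lists passed in C9 against H9, 1 of them with an estimated correlation too. Between the clones, 4529 of 13297 genes passed in limma, 2574 higher and 1955 lower, and 52 of them changed by a fold of 2 or more, 2 higher and 50 lower. Of the calls 56.8% were higher in C9, or 40.6% after median-of-ratios scaling. The count of calls fell to 2819 without C9 replicate 1 and to 2700 without H9 replicate 2. For S91KY191F ESCs against both clones, Emb was at 2.7, Sulf1 at 2.56 and Myrf at 2.39, and Grin1 was at -2.67, Slc24a5 at -2.62 and Nupr1 at -2.41. In that comparison, 7934 of 13297 genes passed in limma, 3801 higher and 4133 lower, and 461 of them changed by a fold of 2 or more, 180 higher and 281 lower. Of the calls 47.9% were higher, or 52.9% after quantile normalization. For the formative and primed epiblast there, of 17 genes, 17 rose and 0 fell (the same numbers adjusted over the list alone), with adjusted p = 1.31e-10 and adjusted p = 0.1002 with an estimated correlation. For the integrated stress response there, of 18 genes, 1 rose and 17 fell (the same numbers adjusted over the list alone), with adjusted p = 7.46e-10 and adjusted p = 0.1002 with an estimated correlation. Of 19 neuroectoderm and eye field genes there, 13 rose and 2 fell (the same numbers adjusted over the list alone), with adjusted p = 3.75e-04 and adjusted p = 0.293 with an estimated correlation. Among 78 cytosolic ribosomal proteins there, 17 rose and 41 fell (19 and 41 adjusted over the list alone), with adjusted p = 0.0347 and adjusted p = 0.670 with an estimated correlation. Among 25 cell cycle and proliferation genes there, 15 rose and 4 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0255 and adjusted p = 0.545 with an estimated correlation. In the 2-cell-like list there, of 8 genes, 0 rose and 0 fell (the same numbers adjusted over the list alone), with adjusted p = 0.422. Of 20 imprinted genes there, 12 rose and 3 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0347 and adjusted p = 0.293 with an estimated correlation. Among 10 feeder and fibroblast genes there, 2 rose and 7 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0161 and adjusted p = 0.271 with an estimated correlation. For trophoblast there, of 15 genes, 5 rose and 6 fell (5 and 7 adjusted over the list alone), with adjusted p = 0.476.

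DKO cells with S91KY191F were compared as EBs and as ESCs (1 library against 2). EBs were higher in Car14, a carbonic anhydrase, at a log2 fold change of 5.55 ± 0.0887 (SE, adjusted p = 4.63e-15). Enpp2, which encodes autotaxin, was at 5.06, Epha1, an ephrin receptor, at 4.86, and Fgf5, a marker of the primed epiblast, at 4.84. The contractile genes Acta2, at -6.0 ± 0.0826 (SE, adjusted p = 1.34e-15), and Tagln, at -5.42, were lower in EBs. The water channel Aqp3 was at -5.51, the autophagy receptor Calcoco2 at -5.44 and Rpl10l at -5.37, uncertain as a close copy of Rpl10. Exosc6, an exosome subunit, is listed at 0 in both ESC libraries and at 42.6 FPKM in the EB library.

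Of 22 naive and general pluripotency genes in EBs against ESCs, 0 rose, 22 fell and 0 did not pass (the same numbers adjusted over the list alone), with adjusted p = 1.09e-10 and adjusted p = 0.153 with an estimated correlation. Tfcp2l1 was at -4.63 and Zfp42 at -4.45. For the formative and primed epiblast, of 17 genes, 14 rose and 2 fell (the same numbers adjusted over the list alone), with adjusted p = 1.06e-06 and adjusted p = 0.153 with an estimated correlation. Of 19 germline genes in EBs against ESCs, 2 rose and 17 fell (the same numbers adjusted over the list alone), with adjusted p = 4.33e-04 and adjusted p = 0.153 with an estimated correlation. Of 22 glycolysis and hypoxia response genes, 15 rose and 5 fell (the same numbers adjusted over the list alone), with adjusted p = 4.72e-04 and adjusted p = 0.291 with an estimated correlation. Of 78 cytosolic ribosomal proteins, 28 rose and 7 fell (24 and 7 adjusted over the list alone), with adjusted p = 0.0405 and adjusted p = 0.915 with an estimated correlation. In the Hox clusters, of 4 genes, 0 rose and 4 fell (the same numbers adjusted over the list alone), with adjusted p = 0.0405 and adjusted p = 0.249 with an estimated correlation. Of 10 feeder and fibroblast genes, 2 rose and 6 fell (the same numbers adjusted over the list alone), with adjusted p = 0.132. Over all genes, 9845 of 13297 genes passed in limma, 4138 higher and 5707 lower, and 2891 of them changed by a fold of 2 or more, 1117 higher and 1774 lower. Of these calls 42% were higher, or 51.1% after quantile normalization, which moved the median of all genes from -0.093 to 0.017.

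Vector-carrying DKO EBs were set against DKO-A and DKO-B, a comparison in which the read layout changes with the group and cannot be separated from it. The mitochondrial mRNA mt-Nd3 had a log2 fold change of -9.08 ± 0.0814 (SE, adjusted p = 2.01e-17). The libraries listed mt-Atp6 at 17.6 and 19.9 FPKM with vector and between 7905 and 8858 FPKM in DKO-A and DKO-B. Exosc6 was at 41.6 and 36.7 FPKM with vector and at 1.00e-06 or listed at 0 in DKO-A and DKO-B. Rps2 at 3.02 and Hist1h2ad at 3.11 were higher and are uncertain because of near-identical copies. In all, 14 of 21 lists passed in vector against DKO, 0 of them with an estimated correlation too. In this comparison, 10064 of 13297 genes passed in limma, 4468 higher and 5596 lower, and 1406 of them changed by a fold of 2 or more, 435 higher and 971 lower. Of the calls 44.4% were higher, or 55.3% after median-of-ratios scaling and 73% after rescaling to a common sum. These moved the median of all genes from -0.046 to 0.056 and 0.303.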

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

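The overlap of human gene models with mouse exons and the removal of length and level trends were chosen after the result was seen. The other tests here were set before their values were computed, although values already seen in these data had prompted them.

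The data of EB DKO S91KY191F replicate 2, used in no comparison, hold human gene models, of which 272 of 58382 genes reach 1 FPKM, with an FPKM sum of 6206. Of 259 such genes on chromosomes 1 to 19 and X, 93.4% overlap an exon of a mouse gene expressed in replicate 1, against 26.6% after a move by 1 Mb. Human genes at positions a mouse genome lacks were above 0 in 0 of 9235 cases, against 9.01% of 48533 others. This argues against reads aligned to the human genome. It does not test which cells the reads came from, since mouse or human reads aligned to a mouse genome would both give 0 there. A candidate explanation is that alignments to the mouse genome were counted at human gene coordinates. The implied depth was 37.7 M here and in replicate 1, and whether both come from one library was not settled.

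DKO-A and DKO-B differed in their change from parental EBs by a test of the difference itself. Germline genes differed by a median log2 fold change of -1.283 for A minus B (adjusted p = 0.0221 with an estimated correlation). Glycolysis and hypoxia response genes differed by 0.884 (adjusted p = 0.0313 with an estimated correlation).

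In EB S91KY191F against vector, germline genes passed with an estimated correlation (adjusted p = 0.0112) and glycolysis genes did not (adjusted p = 0.0807). Across genes, which are not independent replicates, its log2 fold changes correlated with those of DKO-A against DKO-B, from separate libraries, at a Spearman rho of 0.709 and a Pearson r of 0.705, among 10 comparisons correlated with it. With S91KY191F against wild-type WDR5 in ESCs rho was -0.122, but that comparison has no group without WDR5, so the bound set beforehand was wrong. Removing trends on transcript length and expression level left a rho of 0.705, which argues against these. A difference between lines may underlie much of the EB comparison, and an effect of the mutant, in EBs alone or in ESCs too, stays open with 1 library.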

How the results depend on the processing

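Alternatives with clone C9 or H9 alone, without chromosome 8, without genes listed at 0 in a library, and with a longest transcript of at least 1000 nt were chosen after the data were seen. Leaving out chromosome 8 or the 26 genes listed at 0 removes few genes, so counts there could hardly move by 1.5 times. In the alternatives chosen afterwards, all 70 counts of genes stayed within 1.5 times of those reported. Of the counts in the alternatives set before, 337 did so and 23 did not. The cause was not tested, except that a smaller pseudocount by construction shrinks low genes less. With a pseudocount of 0.1, genes with a fold of 2 or more numbered 3134 for EB DKO against parental, 1122 for EB S91KY191F against vector, 654 for ESC S91KY191F against WDR5-WT, 1580 for the rescue against p53 knockout and 4398 for S91KY191F EB against ESC. The secondary comparisons gave 1236 for DKO-A against B, 268 for C9 against H9, 2412 for vector against DKO, 1098 for ESC S91KY191F against p53 knockout, 2658 for A against parental and 3932 for B against parental. A pseudocount of 0.5 gave 580 for EB S91KY191F, 319 for ESC S91KY191F, 663 for A against B and 94 for C9 against H9. Rescaling to a common sum gave 689, 372, 663 and 105 for these, 2357 for vector against DKO and 755 for ESC S91KY191F against p53 knockout. Leaving out a replicate moved the calls of C9 against H9 to between 2700 and 3122, and a lone sample left in a group is assumed to vary like the other groups. The log2 fold change of mt-Co3 in EB DKO against parental was below 0, at -0.0645 (adjusted p = 0.537) without EB parental replicate 1, which lists it at 0. Without replicate 2 the value of 12.901 rests on that listed 0 and is not a measured fold. Trp53 in EB S91KY191F against vector passed with only the compared groups in the fit (adjusted p = 0.0321). Single genes were followed across the alternatives only for the named genes of the main comparisons. Among these, calls were lost in at least 1 alternative for Zscan4f and mt-Co3 in EB DKO against parental. The same held for Zscan4e in S91KY191F EB against ESC, and for mt-Co2 and Rpl17 in the rescue against p53 knockout. The Trp53 fold of the rescue was -0.70 with clone C9 alone and -2.36 with H9 alone. Of 105 list results, an estimated correlation ended 29 calls, median-of-ratios scaling 1 and the replicate block 3. With the replicate number as a block, calls were 10310 for EB DKO against parental, 6368 for EB S91KY191F against vector, 5596 for ESC S91KY191F against WDR5-WT and 8311 for the rescue. Replicate differences correlated between groups at -0.197 to 0.155 over 28 pairs, which shows no strong pattern shared by replicate number. Whether replicates of the same number were handled together is not given in the sources used here. The split into higher and lower genes depends on the scaling in both S91KY191F comparisons too. In EB S91KY191F against vector, the median of all genes was -0.04, or -0.105 after rescaling to a common sum and 0.002 after quantile normalization. In ESC S91KY191F against WDR5-WT, 46.2% of calls were higher, or 40.1% and 49.2% with these scalings. Low genes are limited by depth, which is known here only as implied totals.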

Other observations

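The chromosome 8 tests of an extra copy, of a few genes and of Wdr5 loss, the share of calls on other chromosomes and the test of 6 comparisons without parental EBs were chosen after 20 chromosomes had been examined in 11 comparisons and the result was seen.

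Expressed genes of chromosome 8 (450 with a mean of at least 5 FPKM) had a median log2 fold change 0.417 above that of all other genes in EB DKO against parental (bootstrap 95% interval 0.351 to 0.479; the largest value elsewhere was -0.106). Of these genes 74.2% lay above the median of the others, so most of them took part in the shift. A shift of the median already implies this in large part, so it is no independent test against a few strongly changed genes. An extra copy of most of the chromosome in the knockout lines is a candidate explanation (a change from 2 to 3 copies would give 0.585), but no DNA was measured, the 22 genes of the first 10 Mb lay at -0.064, and in groups of the other layout more stretches lay near or below 0 (vector -0.269 and H9 0.029 at 90 to 100 Mb, vector -0.618 for 6 genes at 50 to 60 Mb). The p53 knockout ESC clones, which keep Wdr5 per the labels, lay 0.618 or more above parental EBs, from which they differ in state and layout too. The shift with state was -0.054 (S91KY191F EB against ESC, with 1 EB library). That with layout, vector and line together was 0.117 (EB vector against DKO). Both were smaller, so the clones argue against loss of Wdr5 as the whole cause only if these values stand for state and layout. Loss of p53 and the history of the lines stay open beside the 0.417.

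For the many genes called between lines of one state, a whole-chromosome difference was set beforehand to show as a shift of 0.3 or more, which was reached at 0.428 (chromosome 8, DKO-A against parental). Against parental EBs, 94.5% to 94.7% of calls lay on other chromosomes, where a direct dose of chromosome 8 genes does not act. The share was 94.3% to 95.1% over the 10 comparisons within one state, also where chromosome 8 was not shifted. It therefore follows the chromosome's share of genes, and the test could not have come out otherwise. Indirect effects of chromosome 8 were not tested and stay open. In the 6 comparisons within one state and layout without parental EBs, each with 4529 to 8374 calls, no chromosome lay more than 0.122 from the others. The bootstrap 95% bounds reached 0.143, which argues against a whole-chromosome shift of 0.3 or more there. Smaller shifts occurred, such as 0.122 for chromosome 16 in C9 against H9 (interval 0.093 to 0.134), and their cause was not tested.

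In vector against DKO, where the read layout changes, genes under 1000 nt lay -0.423 from those of 3000 nt or more. The test set beforehand also asked for under 0.1 in size in each main comparison, all within one layout, which values of -0.138 for EB DKO against parental and 0.106 for ESC S91KY191F against WDR5-WT did not meet. Of the other comparisons within one layout, C9 against H9 lay at -0.223, so an effect of layout through length stays open.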
